A study of Mus musculus with 8 samples.

How the data were processed

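Gene expression was measured on 8 Affymetrix arrays, 1 for each sample of splenic B cells. The labels' protocols state that CD19-positive cells were taken from spleens of 8-week-old C57BL/6 mice with magnetic beads and that total RNA was extracted with TRIzol. The labels give 4 genotypes with 2 biological replicates each. All carry CD19-Cre, a recombinase expressed in B cells, and are called control (CD19-Cre alone), InkArf (with Ink/Arf), Kras (with KrasG12D) and KrasInkArf (with both). The labels do not describe the Ink/Arf allele, the sex of the mice or the day on which each sample was handled. They do not state whether a sample came from 1 mouse or several.

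The deposited values are log2 signals per probe set, and the authors made them with the affy package and RMA, per the submitters' processing notes, whose versions were not given in the sources used here. RMA corrects background, makes the distributions of the arrays equal by quantile normalization and summarises the probes of a set on the log2 scale. It draws together arrays whose total RNA content differs, and it compresses differences of dim probe sets. Array medians lay between 5.14 and 5.23. Correlations between arrays lay between 0.973 and 0.994 over 28 pairs, and no pair of arrays held identical values. The number of arrays limits the precision.

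The table held 45101 probe sets, 64 of them array controls. The platform's probe table paired 34945 probe sets with 1 gene symbol, which were used. It paired 932 with several symbols and gave none for 9160, and these entered only the test of every probe set. Of the 34945, 34741 matched a gene in the RefSeq table of assembly GRCm38.p6 by gene ID, and 0 symbols changed. That table served only for names and for the order of genes, since no build is named for the array. Each gene was represented by its probe set with the highest mean over all 8 arrays, which gave 18193 genes, of which 9010 had more than 1 probe set. No filter on dim genes was applied. Probe sets of Kras and Cd19 were not named by the probe table, so these 2 genes were not analysed here.

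Differences between genotypes were tested with limma 3.58.1 in R 4.3.3. All 8 arrays entered 1 fit of 4 group means with 4 residual degrees of freedom, and eBayes with a trend moderated the variances with 4.61 prior degrees of freedom. There were 8 comparisons: each altered genotype against control, KrasInkArf against InkArf and against Kras, the Kras difference averaged over both backgrounds, the InkArf difference averaged likewise, and the interaction. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes within a comparison, with a threshold of 0.05. Log2 differences are given with their SE from the fit, and group levels with the SD of 2 arrays.

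Before the data were examined, 22 gene lists were fixed, of which 21 were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists within a comparison. The lists covered ERK output and feedback, p53 targets, cell cycle and DNA replication, MYC targets and ribosome biogenesis, glycolysis, the unfolded protein response, the interferon response, NF-kB and B-cell activation, immediate early and stress genes, class II antigen presentation and B-cell identity. Others held genes of follicular, marginal zone, B-1, precursor and transitional, germinal centre and plasma cells, and markers of T and NK cells, of monocytes, macrophages and dendritic cells, of neutrophils, and of erythroid cells and platelets. The sex-linked list was described only. Camera with an estimated correlation and fry were also run, and 0 lists passed in any comparison with either of them.

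The rule for the genes named in the text was fixed at the same time. It took the 12 highest and 12 lowest log2 differences among genes that passed in the comparisons against control, and 5 and 5 in the others. Where no gene passed, it took the 3 highest and 3 lowest by moderated t as values. It added Kras, Cdkn2a, Cdkn2b and Cd19, and up to 4 members of each list with the largest difference. Genes outside it are said to have been chosen after their values were seen.

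The fit and camera were checked on simulated data for Kras against control, drawn for the 18193 genes from their means and residual SDs. Genes were drawn independently of each other, so the check does not cover lists whose members vary together. Of 100 genes shifted by 1 on the log2 scale 72 passed, and of 100 shifted by 2 96 passed, with 8 calls among unchanged genes. With 200 genes shifted at once the adjusted threshold is easier to pass. These shares therefore do not carry over to comparisons in which few genes differ. A list shifted by 0.5 had an adjusted p of 3.0e-06 with camera, 0.0839 with an estimated correlation and 0.0210 with fry. Camera also called 3 unshifted lists.

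Gene counts were also computed with the mean of all probe sets of a gene, only genes above the median mean of 5.88, a further quantile normalization, median centring, eBayes without trend or with trend and robust, the replicate number as a block, only the 2 groups compared, and each array left out in turn. Where an array is left out, its group has 1 sample, which is assumed to vary like the others. Chosen after seeing the data were the Xist level as a covariate, array weights, and a test of every probe set. The block and array weights were applied to gene and list counts, and median centring, the eBayes settings and every probe set to gene counts alone. The fit of the 2 groups compared was limited to gene counts of the comparisons between genotypes. The correlation between backgrounds was recomputed with the mean of probe sets, the filter, the further quantile normalization, the Xist covariate and each array left out. Figures were drawn with Python 3.11.15.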

Results

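The series profiled B cells from spleens of 8-week-old mice described as pre-malignant, with 2 arrays for each of 4 genotypes. KrasG12D is an activated form of the small GTPase Kras, which signals through the ERK cascade. The Ink/Arf locus encodes cell cycle inhibitors and an activator of p53. The design asks what KrasG12D does in B cells, what the Ink/Arf genotype does, and whether either depends on the other. Array medians were 5.15 and 5.18 in control, 5.23 and 5.22 in InkArf, 5.14 and 5.16 in Kras, and 5.19 and 5.18 in KrasInkArf.

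Cdkn2a, the gene of the Ink/Arf locus that encodes p16Ink4a and p19Arf, was dim in every genotype. Its log2 signal was 4.26 ± 0.01 (SD, n = 2) in control, 4.41 ± 0.09 in InkArf, 4.35 ± 0.01 in Kras and 4.30 ± 0.14 in KrasInkArf. Cdkn2b, its neighbour, lay between 3.71 and 3.88 in the group means. Both lay below every array's median, so these probe sets could not show a loss in the InkArf samples, and what part of the locus is altered is not described in the labels.

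The samples differed in sex-linked transcripts in a way that follows the genotypes in part. Xist, the RNA of the inactive X chromosome, was 6.58 and 6.65 in control, 6.69 and 12.51 in InkArf, 12.69 and 12.47 in Kras, and 6.87 and 12.51 in KrasInkArf. The Y-linked gene Eif2s3y was 6.73 and 7.23 in control, 6.17 and 2.95 in InkArf, 2.82 and 2.90 in Kras, and 6.41 and 2.84 in KrasInkArf. Both control arrays thus lay on one side and both Kras arrays on the other, and sex and genotype go together in that comparison.

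Kras replicate 1 stood apart from the other arrays. The first principal component held 40.6% of the variance and placed it at 46.0, against values from -13.5 to 2.30 for the other 7. In it, 262 genes lay at least 1 log2 unit above all other arrays. Ngp, a neutrophil granule protein, was 13.80 there and at most 10.17 elsewhere. Rgs13, a regulator of chemokine signalling in germinal centre B cells, was 9.04 and at most 4.66 elsewhere. Neutrophil markers lay on average 2.77 above the mean of all arrays, germinal centre genes 1.97, cell cycle genes 1.60, monocyte and macrophage markers 0.77 and T and NK markers 0.71. B-cell identity genes lay at -0.27 and follicular genes at -0.72. In Kras replicate 2 the neutrophil markers were at -0.05, the germinal centre genes at -0.36 and the monocyte and macrophage markers at 0.32.

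**Figure D1:**
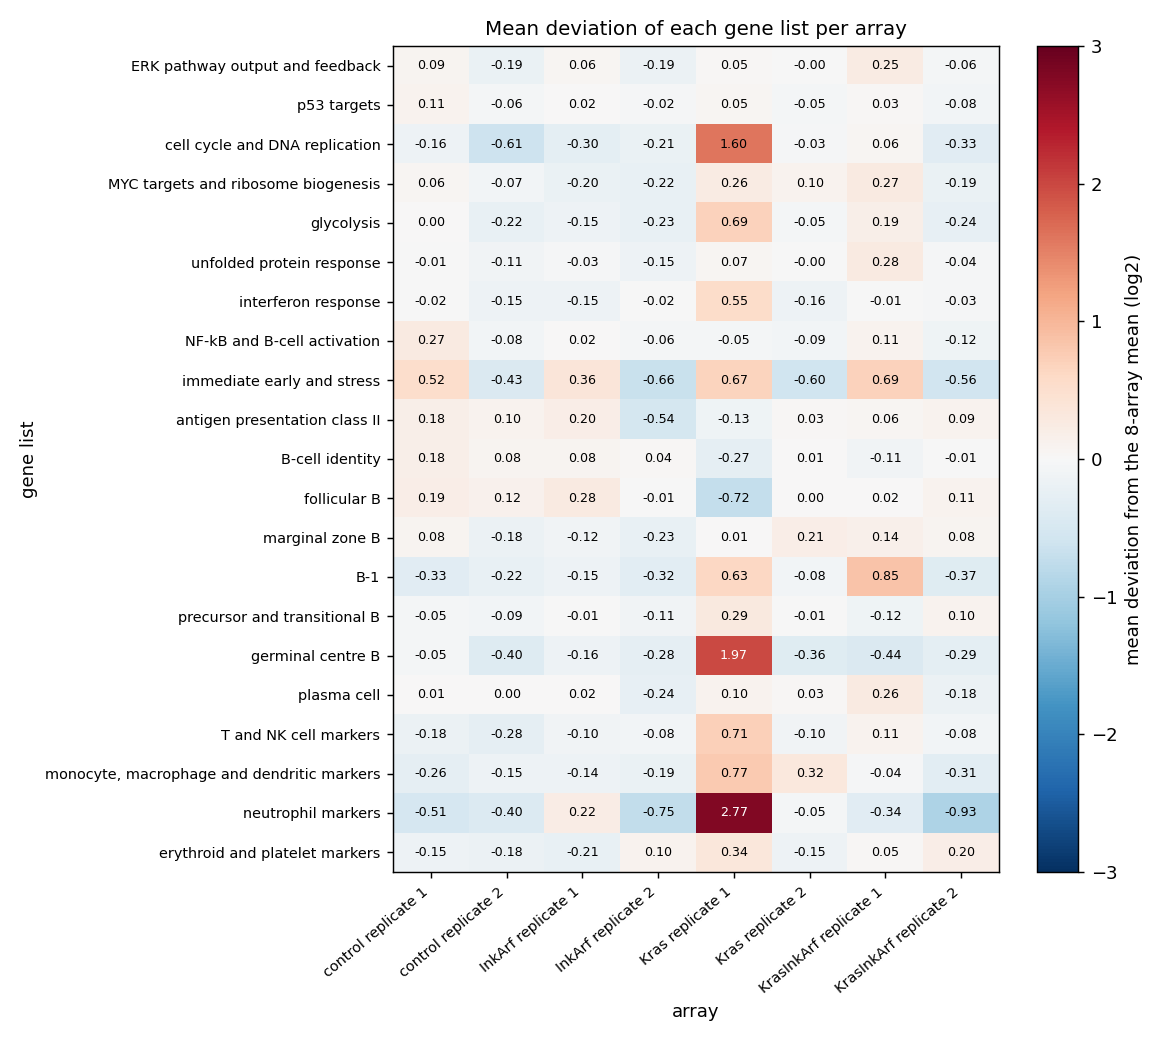
Mean deviation of each tested gene list (rows) in each array (columns), in log2 units from the mean of the 8 arrays, with the value printed in each cell. Kras replicate 1 holds the highest values for neutrophil markers (2.77), germinal centre genes (1.97) and cell cycle genes (1.60).

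Kras against control asks what KrasG12D does on an intact background. Myb, a transcription factor of early lymphoid development, rose from a mean of 4.76 ± 0.20 (SD, n = 2) in control to 7.31 and 6.70 in the Kras arrays, a log2 difference of 2.25 ± 0.20 (SE) or 4.74-fold (limma adjusted p = 0.0394). Its other probe sets gave between 1.34 and 1.81. Fcna, which encodes the lectin ficolin A, rose from 8.15 ± 0.14 to 9.58 ± 0.01, a difference of 1.43 ± 0.14 or 2.69-fold (limma adjusted p = 0.0394). No gene fell. At an unadjusted p under 0.05 there were 1333 genes, 717 higher and 616 lower, where chance gives 909.7. Kras replicate 1, which stood apart, enters this count. Without it the count was not above chance, in a fit that leaves 1 Kras array. Without Kras replicate 1, Myb (1.94 ± 0.18, adjusted p = 0.0133) and Etv5, an ETS factor induced by ERK signalling (1.78 ± 0.17, adjusted p = 0.0133), passed, and Fcna had 1.44 ± 0.18 (adjusted p = 0.112). No gene passed without control replicate 2, where Myb had 2.10 ± 0.25 and Fcna 1.53 ± 0.16. None passed without either InkArf array or either KrasInkArf array, although those arrays do not enter the difference, which stayed at 2.25 for Myb and 1.43 for Fcna. Without control replicate 1 the gene that passed was Apobec3, lower by log2 (-2.88 ± 0.18), with Myb at 2.39 ± 0.25 and Fcna at 1.33 ± 0.16, and without Kras replicate 2, which leaves Kras replicate 1 alone in its group, 533 passed. With the Xist level as a covariate 0 passed, at 2.25 ± 0.31 for Myb and 1.29 ± 0.20 for Fcna, because the covariate follows these genotypes and widens the errors. When only the Kras and control arrays were fitted, the 2 genes that passed were Xist and Eif2s3y. Xist, Eif2s3y and Apobec3 were named after their values were seen.

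**Figure D2:**
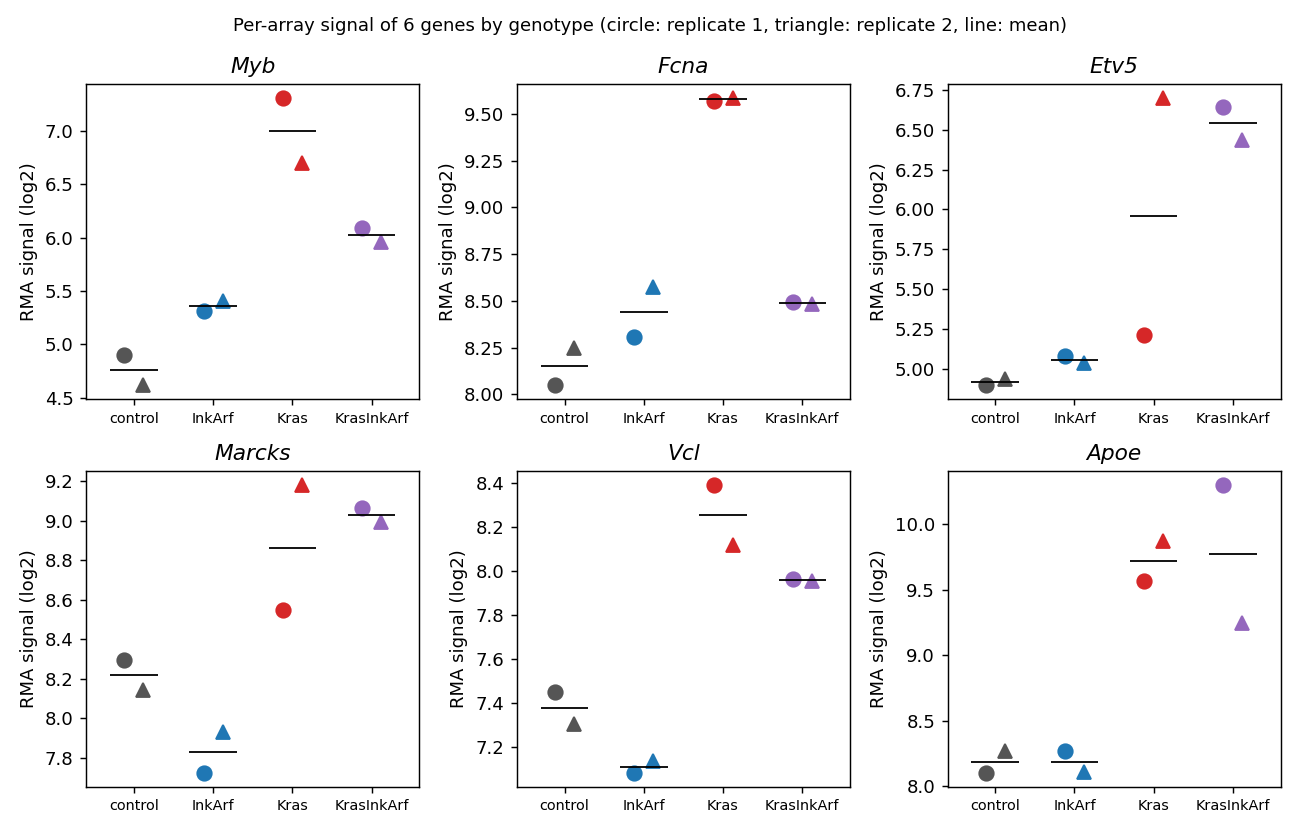
RMA signal (log2) of Myb, Fcna, Etv5, Marcks, Vcl and Apoe in each array by genotype, with circles for replicate 1, triangles for replicate 2 and lines for group means. Myb is 4.90 and 4.62 in control and 7.31 and 6.70 in Kras, and Etv5 is 5.21 in Kras replicate 1 and 6.70 in Kras replicate 2.

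Of the lists, 9 passed camera as higher in Kras and 3 as lower. The markers of monocytes, macrophages and dendritic cells were higher in 16 of 16 members with a mean of 0.75 (adjusted p = 2.72e-12, and adjusted p = 0.292 with an estimated correlation). None of them passed over all genes, while 7 were higher when adjusted over the list alone. Among them were the adhesion molecule Vcam1 (1.45 ± 0.23), the complement component C1qa (1.33 ± 0.24) and the haem-degrading enzyme Hmox1 (1.25 ± 0.20). Neutrophil markers were higher in 10 of 11 (mean 1.81, adjusted p = 3.93e-06), with Lcn2 at 3.61 ± 1.18 and Camp at 3.10 ± 1.04. T and NK markers were higher in 11 of 14 (mean 0.53, adjusted p = 0.00344, and adjusted p = 0.340 with an estimated correlation). Cell cycle genes were higher in 27 of 29 (mean 1.17, adjusted p = 4.49e-15), with Mki67 at 2.58 ± 0.79 and Top2a at 2.36 ± 0.74, while control replicate 2 held the lowest mean of that list (-0.61) of all arrays. Germinal centre genes were higher in 9 of 9 (mean 1.03, adjusted p = 9.29e-04), with Rgs13 at 2.19 ± 1.28 and Gcsam at 1.94 ± 0.92. For these 3 lists the adjusted p was 0.478 with an estimated correlation. Kras replicate 1 gave much of these means: without it they were 0.40 for neutrophil markers (adjusted p = 0.153), 0.13 for T and NK markers (adjusted p = 0.287), 0.35 for cell cycle genes (adjusted p = 2.89e-06) and -0.14 for germinal centre genes (adjusted p = 0.287). Without Kras replicate 2 they were 3.22, 0.93, 1.98 and 2.19. T and NK markers also missed the threshold without control replicate 2 (adjusted p = 0.0517).

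Glycolysis genes were higher in 10 of 11 (mean 0.43, adjusted p = 5.43e-04), MYC targets in 17 of 20 (mean 0.18, adjusted p = 9.31e-04), interferon response genes in 15 of 17 (mean 0.28, adjusted p = 0.00332) and B-1 genes in 8 of 9 (mean 0.55, adjusted p = 0.0141). The B-1 member with the largest value was Itgam (2.83-fold), an integrin that myeloid cells also carry, and its log2 difference was 0.00 without Kras replicate 1. B-cell identity genes were lower in 13 of 14 (mean -0.26, adjusted p = 9.06e-04), among them Ebf1 (-0.65 ± 0.25) and Cd22 (-0.42 ± 0.16). Follicular genes were lower in 5 of 5 (mean -0.51, adjusted p = 0.00344), 1 of them when adjusted over the list alone, with Ccr7 at -0.77 ± 0.22, and class II genes in 8 of 9 (mean -0.19, adjusted p = 0.0317). For each of these 7 lists the adjusted p was 0.478 with an estimated correlation. None of the 7 passed without Kras replicate 1, where interferon response genes turned to -0.07 (adjusted p = 0.423). The means were then 0.06 for glycolysis (adjusted p = 0.471), 0.10 for MYC targets (adjusted p = 0.153), 0.20 for B-1 (adjusted p = 0.282), -0.12 for B-cell identity (adjusted p = 0.282), -0.15 for follicular and -0.11 for class II genes (both at adjusted p = 0.423). Without Kras replicate 2 the means were 0.80 for glycolysis, 0.64 for interferon response, 0.91 for B-1, -0.39 for B-cell identity and -0.87 for follicular genes. Without control replicate 1 the B-1 (adjusted p = 0.123) and class II lists (adjusted p = 0.124) missed the threshold. Without control replicate 2 the interferon response (adjusted p = 0.0517) and class II lists (adjusted p = 0.0714) did, and the MYC mean was 0.12.

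The lists that passed without Kras replicate 1 were the monocyte and macrophage markers (mean 0.53, adjusted p = 1.23e-09), the cell cycle genes (mean 0.35, adjusted p = 2.89e-06) and the marginal zone genes (mean 0.26, adjusted p = 0.0104). Each had an adjusted p of 0.787 with an estimated correlation.

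The remaining lists did not pass in Kras against control. ERK output genes were higher in 14 of 24 (adjusted p = 0.329), with Etv5 at 1.04 ± 0.38, and p53 targets in 11 of 19 (adjusted p = 0.959, with a mean of -0.03 and a median of 0.02). NF-kB and activation genes were lower in 13 of 19 (adjusted p = 0.125). In that list 3 were higher and 4 lower when adjusted over the list alone, with Traf1 at -0.80 ± 0.23 and Birc3 at -0.73 ± 0.20. The adjusted p was 0.167 for the unfolded protein response, whose mean was 0.09 and median -0.04 and of which 1 was higher when adjusted over the list alone, 0.125 for marginal zone genes and 0.0999 for precursor and transitional genes. It was 0.497 for plasma cell genes and 0.0879 for erythroid and platelet markers. Immediate early and stress genes had a mean of -0.01, a median of -0.31 and an upward test (adjusted p = 0.748).

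InkArf against control asks what the Ink/Arf genotype does alone. No gene passed with limma, the lowest adjusted p was 0.699, and 1279 genes had an unadjusted p under 0.05. The highest by moderated t were Tmem178 (0.55 ± 0.10), Adamtsl1 (0.73 ± 0.13) and the Y-linked Usp9y (0.56 ± 0.11), and the lowest were Taok3 (-0.78 ± 0.13), Secisbp2l (-0.88 ± 0.16) and Ube2e1 (-0.61 ± 0.12). MYC targets and ribosome biogenesis genes were lower in 16 of 20 (mean -0.20, camera adjusted p = 0.00100, and adjusted p = 0.975 with an estimated correlation), with Rrs1 at -0.63 ± 0.16 and Tsr1 at -0.55 ± 0.20. This was the single list that passed, and it did not with a further quantile normalization or the Xist covariate. The p53 targets were lower in 11 of 19 (adjusted p = 0.837), and the cell cycle gene Ccnb2 had 0.61 ± 0.74. Without InkArf replicate 1, H2-Eb1 (-3.01 ± 0.21), a chain of a class II molecule that presents antigen, and D17H6S56E-5 (-3.76 ± 0.28) passed. Without control replicate 1 Apobec3 did (-3.11 ± 0.18). These genes were named after their values were seen. The list count was then 4 without InkArf replicate 1 and 3 without control replicate 2.

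KrasInkArf against control gave no gene past the threshold with limma (lowest adjusted p = 0.978), and 777 genes had an unadjusted p under 0.05, below the 909.7 that chance gives. The highest by moderated t were Myb (1.27 ± 0.20), Sdf2l1 of the endoplasmic reticulum (0.79 ± 0.14) and the lipid carrier Apoe (1.58 ± 0.29), although the other Myb probe sets gave 0.44 to 0.49. The lowest with names were Zfp82 (-0.92 ± 0.15) and Secisbp2l (-0.95 ± 0.16). Of the ERK output genes, Etv5 had 1.62 ± 0.38, and the phosphatases that oppose ERK, Dusp4 and Dusp6, had 1.06 ± 0.41 and 0.80 ± 0.23, while the list was higher in 13 of 24 (adjusted p = 0.372). Etv5 passed without Kras replicate 1 (adjusted p = 0.00994), without Kras replicate 2 (adjusted p = 0.00898) and when only the 2 groups were fitted (adjusted p = 0.0397). Without control replicate 1 Apobec3 passed (-2.66 ± 0.18).

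B-1 genes were higher in 9 of 9 in KrasInkArf against control (mean 0.52, adjusted p = 0.0139), with Plscr1 at 1.21 ± 0.75, Ctla4 at 0.99 ± 0.44 and Cd5 at 0.87 ± 0.39. The list lay at 0.85 in KrasInkArf replicate 1 and -0.37 in replicate 2. T and NK markers were higher in 13 of 14 (mean 0.24, adjusted p = 0.0464), and B-cell identity genes were lower in 11 of 14 (mean -0.19, adjusted p = 0.0464), with Ebf1 at -0.79 ± 0.25. All 3 lists had an adjusted p of 0.899 with an estimated correlation. The count of 3 lists became 0 without control replicate 2, 1 without control replicate 1, 5 without either Kras array, 7 without KrasInkArf replicate 2, 6 with the Xist covariate and 0 among genes above the median mean. Without KrasInkArf replicate 1 the B-1 mean turned to -0.09 (adjusted p = 0.920), T and NK markers had 0.14 (adjusted p = 0.131) and B-cell identity genes -0.14 (adjusted p = 0.295). Without KrasInkArf replicate 2 the B-1 mean was 1.13. Without control replicate 1, and likewise without control replicate 2, all 3 lists missed the threshold, while their means kept their direction and most of their size.

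KrasInkArf against InkArf asks for the KrasG12D difference on the Ink/Arf background. No gene passed with limma (lowest adjusted p = 0.767), and 1168 had an unadjusted p under 0.05. The highest by moderated t were the cytoskeletal genes Vcl (0.85 ± 0.14) and Marcks (1.20 ± 0.20), and Ly6k (1.38 ± 0.24), whose other probe set gave -0.09. The lowest were P4ha2 (-0.69 ± 0.12), Setd5 (-0.82 ± 0.14) and Glra4 (-0.66 ± 0.12). Of the ERK output genes 2 were higher when adjusted over the list alone, and Etv5 (1.48 ± 0.38), Dusp4 (1.42 ± 0.41) and Dusp6 (0.90 ± 0.23) had the largest values, while the list was higher in 13 of 24 (adjusted p = 0.505). Etv5 passed without Kras replicate 1 (adjusted p = 0.0223) and without Kras replicate 2 (adjusted p = 0.0202). Without InkArf replicate 1, H2-Eb1 (2.98 ± 0.21) and D17H6S56E-5 (3.47 ± 0.28) passed, and with only the 2 groups fitted, Ppbp did (1.90, adjusted p = 0.0261).

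On that background MYC targets were higher in 20 of 20 (mean 0.25, adjusted p = 1.05e-05), with the nucleolar protein Fbl at 0.72 ± 0.18. Marginal zone genes were higher in 9 of 12 (mean 0.28, adjusted p = 0.00640), with the receptor S1pr3 at 1.14 ± 0.32 and Cd36 at 0.58 ± 0.19. Genes of the unfolded protein response were higher in 8 of 13 (mean 0.21, adjusted p = 0.00921), with Hsp90b1 at 0.72 ± 0.27 and Manf at 0.53 ± 0.18. B-1 genes were higher in 8 of 9 (mean 0.47, adjusted p = 0.0114) and plasma cell genes in 10 of 12 (mean 0.15, adjusted p = 0.0198). All 5 lists had an adjusted p of 0.895 with an estimated correlation. KrasInkArf replicate 1 gave most of 4 of them: without it MYC targets averaged 0.02 (9 of 20 higher, adjusted p = 0.737), the unfolded protein response 0.05 (adjusted p = 0.374), B-1 genes -0.13 (adjusted p = 0.982) and plasma cell genes -0.07 (adjusted p = 0.951). Without KrasInkArf replicate 2 these means were 0.47, 0.37, 1.08 and 0.37. Without InkArf replicate 2 marginal zone genes and the unfolded protein response were at adjusted p = 0.0801, B-1 genes at 0.0952 and plasma cell genes at 0.242 (mean 0.02), and without InkArf replicate 1 the plasma cell mean was 0.28. The count of 5 became 1 without KrasInkArf replicate 1, 2 without InkArf replicate 2, 8 without either Kras array (with neutrophil markers lower, at a mean of -0.37 and adjusted p = 0.0199, without Kras replicate 1, and adjusted p = 0.696 with an estimated correlation), 3 with a further quantile normalization and 1 among genes above the median mean.

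KrasInkArf against Kras asks what the Ink/Arf genotype adds to KrasG12D. No gene passed with limma (lowest adjusted p = 0.660), and 800 had an unadjusted p under 0.05. The lowest by moderated t were Fcna (-1.09 ± 0.14), Vcam1 (-1.60 ± 0.23) and Csf1r, the receptor of the macrophage growth factor (-1.02 ± 0.15). The highest were Jkamp (1.11 ± 0.18, and -0.08 to 0.97 for its other probe sets), Crygb (0.48 ± 0.09) and Usp9y (0.49 ± 0.11). Monocyte and macrophage markers were lower in 14 of 16 (mean -0.72, adjusted p = 5.61e-13, and adjusted p = 0.255 with an estimated correlation), 7 of them when adjusted over the list alone. Neutrophil markers were lower in 11 of 11 (mean -1.99, adjusted p = 6.04e-09), 5 of them when adjusted over the list alone, cell cycle genes in 27 of 29 (mean -0.92, adjusted p = 8.07e-13) and germinal centre genes in 9 of 9 (mean -1.17, adjusted p = 1.28e-04). Glycolysis genes (11 of 11), MYC targets (16 of 20) and interferon response genes (14 of 17) were lower too, and follicular genes were higher in 5 of 5. For these 7 lists the adjusted p was 0.742 with an estimated correlation. Without Kras replicate 1, 3 lists passed. The monocyte and macrophage markers (mean -0.50, adjusted p = 4.41e-11) and the neutrophil markers (mean -0.58, adjusted p = 6.18e-04) were lower, with adjusted p = 0.746 and adjusted p = 0.999 with an estimated correlation. Erythroid and platelet markers were higher (mean 0.27, adjusted p = 0.00495, and adjusted p = 0.999 with an estimated correlation), against 0.03 (adjusted p = 0.860) with all arrays, while germinal centre genes averaged -0.01 and cell cycle genes -0.11 (adjusted p = 0.152). Glycolysis then turned to 0.02 (adjusted p = 0.999) and interferon response genes to 0.14 (adjusted p = 0.0886), and the means were 0.06 for follicular genes and -0.06 for MYC targets (adjusted p = 0.256). With KrasInkArf replicate 2 left out, MYC targets turned to 0.09 (adjusted p = 0.365), glycolysis had -0.14 (adjusted p = 0.183) and follicular genes were at adjusted p = 0.0720. With KrasInkArf replicate 1 left out, interferon response genes were at adjusted p = 0.0883, and the means were -0.37 for MYC targets and -0.56 for glycolysis. Without Kras replicate 2, 435 genes and 13 lists passed, and the means were -3.41 for neutrophil markers, -1.73 for cell cycle and -2.34 for germinal centre genes, -0.72 for glycolysis, -0.57 for interferon response, -0.22 for MYC targets and 0.78 for follicular genes.

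Averaged over both backgrounds, 4 arrays with KrasG12D were set against 4 without. Sex enters this average in part, since both Kras arrays were high and both control arrays low in Xist, while InkArf and KrasInkArf each held an array of either kind. No gene passed with limma, the lowest adjusted p was 0.0813, and 1956 genes had an unadjusted p under 0.05. The highest by moderated t were Myb (1.45 ± 0.14), Vcl (0.86 ± 0.10) and Apoe (1.56 ± 0.21), and the lowest were Cpne4 (-1.18 ± 0.16), the kynurenine pathway enzyme Kynu (-0.70 ± 0.10) and the prostaglandin synthase Ptgs2 (-0.51 ± 0.08). The 4 genes that passed without Kras replicate 1 were all higher: Etv5 (1.63 ± 0.11, adjusted p = 0.00109), Myb (1.30 ± 0.12, adjusted p = 0.00820), Marcks (1.08 ± 0.11, adjusted p = 0.0203) and a Riken clone. Without KrasInkArf replicate 2 the 4 that passed were Apoe, Ccr1, Dmxl2 and Pstpip2, and without Kras replicate 2 there were 396. Etv5 was 5.21 in Kras replicate 1, and between 6.44 and 6.70 in the other 3 arrays with KrasG12D, against 4.90 to 5.08 in the 4 without. With trend and robust, Myb and Vcl passed, with a further quantile normalization Myb did, and with the Xist covariate Ccr1 and Hmga2-ps1 did. Ccr1, Dmxl2, Pstpip2 and Hmga2-ps1 were named after their values were seen.

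In the average, 10 lists passed camera as higher and 2 as lower. MYC targets were higher in 20 of 20 (mean 0.21, adjusted p = 1.45e-06), with Fbl at 0.59 ± 0.13 and Npm1 at 0.43 ± 0.14. Marginal zone genes were higher in 8 of 12 (mean 0.22, adjusted p = 0.00762), 2 of them when adjusted over the list alone, and B-1 genes in 9 of 9 (mean 0.51, adjusted p = 0.00173). The unfolded protein response was higher in 7 of 13 (mean 0.15, median 0.00, adjusted p = 0.0133), with Hsp90b1 at 0.65 ± 0.19. Glycolysis (11 of 11), interferon response (14 of 17), cell cycle (27 of 29), T and NK (12 of 14) and monocyte and macrophage genes (13 of 16) were also higher, and B-cell identity (13 of 14) and follicular genes (5 of 5) were lower. For these 11 lists the adjusted p was 0.477 with an estimated correlation. The twelfth, neutrophil markers, was higher in 10 of 11 (mean 0.72, adjusted p = 0.00790, and adjusted p = 0.530 with an estimated correlation). Without Kras replicate 1 the count was 6, with MYC targets (mean 0.17, adjusted p = 1.15e-04) and marginal zone genes (mean 0.27, adjusted p = 3.83e-04) among them, each at adjusted p = 0.656 with an estimated correlation. Neutrophil markers then averaged 0.02 with a median of -0.01, interferon response genes -0.01, cell cycle genes 0.23 and B-1 genes 0.34. None of the lists passed there with an estimated correlation. Glycolysis had 0.11, T and NK markers 0.12 and B-cell identity genes -0.12, each at adjusted p = 0.106, and follicular genes -0.11 (adjusted p = 0.360). Leaving out KrasInkArf replicate 1 gave MYC targets 0.10 (adjusted p = 0.00770), the unfolded protein response 0.07, glycolysis 0.19, B-1 genes 0.21 (adjusted p = 0.0645) and follicular genes adjusted p = 0.0645. Leaving out KrasInkArf replicate 2 gave MYC targets 0.33, B-1 genes 0.82 and the unfolded protein response 0.23. Marginal zone genes were at adjusted p = 0.0668 without Kras replicate 2, where the means were 1.43 for neutrophil markers, 1.05 for cell cycle, 0.52 for T and NK, 0.48 for glycolysis, 0.35 for interferon response and -0.47 for follicular genes. Follicular (adjusted p = 0.156) and interferon response genes (adjusted p = 0.0713) missed the threshold without InkArf replicate 1. So did neutrophil markers without InkArf replicate 2 (mean 0.48, adjusted p = 0.0826), and T and NK (adjusted p = 0.0627) and follicular genes (adjusted p = 0.0795) without control replicate 2. Among genes above the median mean it was also 6.

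The ERK output list did not pass in the average (13 of 24 higher, adjusted p = 0.275), although 2 of its genes were higher when adjusted over the list alone. Its largest values were Etv5 (1.26 ± 0.27), Dusp4 (0.87 ± 0.29) and Dusp6 (0.73 ± 0.16). Of the NF-kB and activation genes, 3 were higher and 5 lower when adjusted over the list alone, with Birc3 at -0.56 ± 0.14 and Ebi3 at 0.49 ± 0.11.

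The KrasG12D differences on the 2 backgrounds share no array. Across genes, which are not independent replicates, their Pearson correlation was 0.291 and Spearman's rho was 0.307, and 61.6% of genes had the same sign. Of the 1333 genes with an unadjusted p under 0.05 in Kras against control, 997 (74.8%) had the same sign on the Ink/Arf background. Both Myb and Fcna were among them by sign. For Fcna the interaction, given below, nearly cancels its difference of 1.43 ± 0.14 in Kras against control. For Myb it takes away most of the difference, which was 2.25 in Kras against control and 1.45 in the average over both backgrounds. The size of neither difference recurred. The correlation was 0.335 without Kras replicate 1 and 0.160 without KrasInkArf replicate 1.

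**Figure D3:**
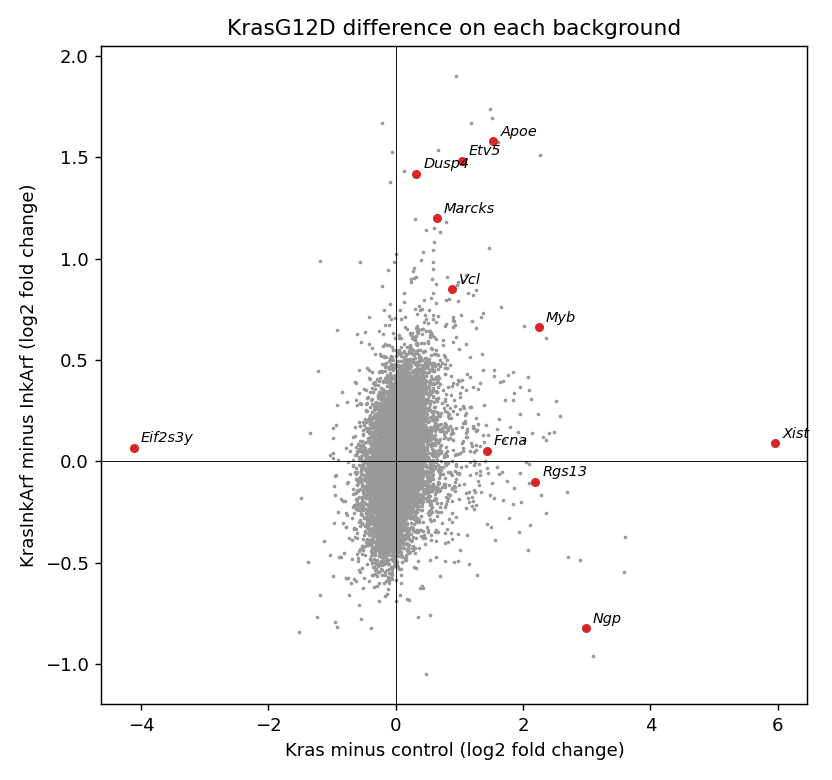
Log2 fold change of Kras minus control (horizontal axis) against KrasInkArf minus InkArf (vertical axis) for each of 18193 genes, with named genes in red. The Pearson correlation across genes is 0.291, and Apoe and Etv5 are higher on both backgrounds, while Ngp is higher on the horizontal axis alone.

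Averaged over both Kras states, the InkArf difference gave no gene past the threshold with limma (lowest adjusted p = 0.564), and 1583 had an unadjusted p under 0.05. The highest by moderated t were Usp9y (0.52 ± 0.08), Jkamp (0.82 ± 0.12) and Spata21 (0.39 ± 0.07), and the lowest with names were Cd302 (-0.52 ± 0.09) and Vcam1 (-0.85 ± 0.16). Lower lists were MYC targets (17 of 20, mean -0.17, adjusted p = 8.79e-05), cell cycle genes (25 of 29, mean -0.39, adjusted p = 8.79e-05), glycolysis (11 of 11, mean -0.22, adjusted p = 0.00368), monocyte and macrophage markers (14 of 16, mean -0.34, adjusted p = 4.38e-05) and neutrophil markers (11 of 11, mean -0.90, adjusted p = 4.31e-04). All 5 had an adjusted p of 0.970 with an estimated correlation. Without Kras replicate 1 the count was 3, of which erythroid and platelet markers were higher (mean 0.19, adjusted p = 0.0231, and adjusted p = 0.917 with an estimated correlation) and MYC targets and the monocyte and macrophage markers lower, with cell cycle genes at a mean of 0.01 (adjusted p = 0.895), neutrophil markers at -0.20 (adjusted p = 0.132), glycolysis at -0.03 (adjusted p = 0.507) and MYC targets at -0.13 (adjusted p = 0.00434, and adjusted p = 0.917 with an estimated correlation). MYC targets averaged -0.06 and glycolysis -0.11 without KrasInkArf replicate 2 (both at adjusted p = 0.139), and MYC targets -0.28 without KrasInkArf replicate 1. Without Kras replicate 2, 271 genes and 9 lists passed, at means of -0.80 for cell cycle genes, -0.40 for glycolysis and -1.61 for neutrophil markers, and with a further quantile normalization 8 lists did.

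The interaction, the KrasG12D difference with Ink/Arf minus that without, gave no gene past the threshold with limma (lowest adjusted p = 1.00), and 558 genes had an unadjusted p under 0.05. The lowest by moderated t were Fcna (-1.38 ± 0.20), Myb (-1.58 ± 0.29) and Pan3 (-1.03 ± 0.19), and the highest were Prss53 (0.77 ± 0.15), the caspase Casp4 (1.24 ± 0.28) and Ly6k (1.46 ± 0.34). Camera called 4 lists lower and 2 higher, and none of them passed with an estimated correlation or with fry. Without Kras replicate 2, 252 genes passed, and without control replicate 1 Apobec3 did (3.32 ± 0.23).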

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

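All tests of explanations in this part were chosen after the results were seen. The difference between arrays with and without KrasG12D varied between the 2 backgrounds for 6 lists by the interaction term with camera. Both control arrays are low and both Kras arrays high in Xist, while InkArf and KrasInkArf each hold an array of either kind. The term therefore also carries a sex difference. With the Xist covariate, camera adjusted p was 0.0464 for germinal centre and at most 1.97e-05 for monocyte and macrophage, neutrophil and cell cycle genes. Lower with Ink/Arf were the monocyte and macrophage markers (16 of 16, mean -0.76, adjusted p = 5.55e-11), the cell cycle genes (27 of 29, mean -1.05, adjusted p = 1.93e-09), the neutrophil markers (10 of 11, mean -2.19, adjusted p = 3.23e-06) and the germinal centre genes (9 of 9, mean -1.18, adjusted p = 0.00166). Higher were class II genes (8 of 9, mean 0.43, adjusted p = 0.00594) and follicular genes (4 of 5, mean 0.44, adjusted p = 0.0491). The adjusted p with an estimated correlation was 0.340 for the monocyte and macrophage markers and 0.750 for the other 5. Without Kras replicate 1, 3 lists passed: the monocyte and macrophage markers (mean -0.54, adjusted p = 8.53e-09), the neutrophil markers (mean -0.78, adjusted p = 0.00122) and the cell cycle genes (mean -0.24, adjusted p = 0.0417), at adjusted p = 0.940 with an estimated correlation. The germinal centre list was then at 0.969 with a mean of -0.01, so most of the cell cycle, neutrophil and germinal centre means came from that array. With Kras replicate 2 left out these means were -1.87, -3.60 and -2.34, and the follicular mean was 0.80. The follicular list was at 0.939 (mean 0.08) without Kras replicate 1, 0.289 without InkArf replicate 2, 0.119 without control replicate 2, 0.0978 without KrasInkArf replicate 2 and 0.0731 without control replicate 1, and also at 0.103 with the mean of all probe sets, 0.0661 among genes above the median mean, 0.0685 with a further quantile normalization and 0.229 with the Xist covariate. The class II list was at 0.526 (mean 0.07) without InkArf replicate 2, and its mean was 0.80 without InkArf replicate 1. It also missed the threshold without Kras replicate 1 or control replicate 1, where its mean stayed positive and not far below 0.43. With the Xist covariate its camera adjusted p was 0.356. The count of lists was 12 without Kras replicate 2, 10 without KrasInkArf replicate 1 and 11 without KrasInkArf replicate 2.

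Kras replicate 1 held transcripts of several kinds of cell. Of the 41 members of the neutrophil, T and NK, and monocyte and macrophage lists, 24 (58.5%) were highest of 8 arrays there, where chance gives 12.5%, and carry-over of non-B cells through the magnetic beads stays open for these genes, since the count restates the pattern and does not test it. The 9 germinal centre genes exceeded the highest other array by 1.86 on average (SE 0.55 over members). Rgs13, Gcsam and Mef2b lay above it by 4.38, 3.36 and 2.50, and S1pr2 by 0.03. All 9 were already highest in that array when the list was singled out, which fixed the sign of the excess. Whether carry-over accounts for these genes is therefore left undecided. The same list differed from control by 2.19 in Kras replicate 1 and by -0.14 (SE 0.07 over members) in Kras replicate 2. This does not decide on an effect of KrasG12D of equal size in both Kras samples. The list was singled out for its high value in replicate 1, and an SE over members holds no spread between mice. The 127 genes over 2 above control in replicate 1 had a median of 0.22 in replicate 2. Their choice on replicate 1 likewise leaves the question undecided. An effect that differs between mice, or a response or early disease in the sample behind Kras replicate 1, stays open and was not tested.

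Myb and Fcna differed between Kras and control, where Xist and genotype go together. Within InkArf and KrasInkArf, the array with high Xist exceeded the other by -0.0165 on average for Myb and 0.13 for Fcna. The genotype differences were 2.25 ± 0.20 and 1.43 ± 0.14. In both pairs the array with high Xist is replicate 2, so a difference by replicate number could offset one by sex. Unless it does, these values argue against sex as the whole cause of either difference. RNA of monocytes and macrophages would make both differences shrink with that list, whose mean differed from control by 0.75 in Kras and 0.03 in KrasInkArf. Myb still differed by 1.27 in KrasInkArf (SE 0.20 for the gene, 0.27 with the error of the list), against that explanation for the probe set used. Part of this 1.27 lies between InkArf and control and is not a KrasG12D difference. The KrasG12D difference of Myb was 2.25 without Ink/Arf and averaged 1.45 over both backgrounds, so it was below 1.27 with Ink/Arf. The other Myb probe sets differed from control by 0.44 to 0.49 in KrasInkArf. Fcna, which is not in the list, differed by 0.34, an excess of 0.28 over the proportion: this is above 2 SE with the error of the gene alone (0.14), the rule used first, and below with that of the list added after the first outcome was seen (0.18), so such cells stay open for Fcna, and a KrasG12D effect in B cells stays open for both.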

How the results depend on the processing

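Array weights, the Xist covariate and the test of every probe set were chosen after seeing the data. Among 52 list calls none turned direction past the threshold, and all 52 were lost with an estimated correlation and with fry; no called gene turned direction. Of the gene and comparison pairs named by rule, 217 changed sign in at least 1 setting without passing in either. Apart from fewer genes, arrays or probe sets in some settings, the cause was not tested. A dim probe set limits what can be seen, as with Cdkn2a.

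The 2 genes of Kras against control became 0 with the mean of all probe sets, among genes above the median mean, with the Xist covariate and with every probe set on its own, and 1 with a further quantile normalization, median centring or array weights, which come out equal within each pair. Myb was 1.80 ± 0.17 and Fcna 1.43 ± 0.13 with the mean of all probe sets (adjusted p = 0.0674), and 2.25 ± 0.31 and 1.29 ± 0.20 with the Xist covariate (adjusted p = 0.641 and 0.697), whose errors are wider. Above the median mean Fcna was 1.43 ± 0.14 (adjusted p = 0.0660), and Myb, with a mean of 5.79, was left out. In the Kras average the 0 genes became 1 with a further quantile normalization, 2 with trend and robust and 2 with the Xist covariate. With only the 2 groups compared, 1 gene passed in KrasInkArf against control and 1 in KrasInkArf against InkArf.

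With each array left out, gene counts ranged from 0 to 533 for Kras against control, 0 to 2 for InkArf against control, 0 to 1 for KrasInkArf against control, 0 to 2 for KrasInkArf against InkArf, 0 to 435 for KrasInkArf against Kras, 0 to 396 for the Kras average, 0 to 271 for the InkArf average and 0 to 252 for the interaction. The counts over 200 came without Kras replicate 2. List counts ranged from 3 to 15, 1 to 4, 0 to 7, 1 to 8, 3 to 13, 6 to 15, 3 to 9 and 3 to 12 in the same order. The correlation of the KrasG12D differences ranged from 0.160 to 0.335.

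The number of lists fell to 0 in all 8 comparisons with an estimated correlation and with fry. A further quantile normalization gave 0 lists for InkArf against control, 3 for KrasInkArf against InkArf and 8 for the InkArf average. Genes above the median mean gave 0 for KrasInkArf against control, 1 for KrasInkArf against InkArf and 6 for the Kras average. The Xist covariate gave 0 for InkArf against control and 6 for KrasInkArf against control.

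Samples that share a replicate number are not known to be paired: the differences of replicate 1 from 2 correlated between groups by 0.07 to 0.25 across genes. With the replicate number as a block, 2 genes passed in the Kras average (Myb and Klhl42) and 2 lists in InkArf against control, and it moved no other count by over 1.5 times.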

Other observations

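All tests in this part were chosen after the results were seen. Immediate early genes varied with the replicate number more than with genotype. When the 4 arrays of replicate 1 were set against the 4 of replicate 2 with limma, 20 genes passed, 14 of them higher in replicate 1, and 6 of these were among the 16 members of the immediate early and stress list. Fosb was higher by 2.82 ± 0.24 (SE), Fos by 2.34 ± 0.30, Dusp1 by 2.27 ± 0.25, Klf4 by 2.06 ± 0.16, and outside the list Egr1 by 1.78 ± 0.18, Ppp1r15a by 1.65 ± 0.17 and Myc by 1.38 ± 0.17. Of the list's heat shock genes, Hspa1b was 8.999 in Kras replicate 1 and at most 4.93 elsewhere.

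The list was higher in replicate 1 by 0.95 in control, 1.02 in InkArf, 1.27 in Kras and 1.26 in KrasInkArf. Sex is argued against by the control and Kras pairs, whose arrays share an Xist state and differed by at least 0.95. RNA quality was read from the log2 ratio of 3′ to 5′ probe sets of actin and Gapdh. That ratio was lower in replicate 1 of InkArf (-0.14, with actin at -0.03 and Gapdh at -0.25). It was higher in the other 3 groups, by 0.52 in control, 0.33 in Kras and 0.02 in KrasInkArf. Each value rests on 1 pair of arrays. RNA quality is thus argued against in InkArf alone and stays open for the other groups. The measure was changed from that count of groups to the lowest difference after the count was seen, with the same reading. Handling shared by the samples of one number, such as the time between dissection and lysis, stays open: the smallest difference of 0.95 (SD over groups 0.16) restates the pattern and does not test it, and the labels name no day. No biological explanation was tested, since no genotype follows the number.

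All 35 splits of the 8 arrays into 4 and 4, the real ones included, were refitted as 2 groups. The Kras split called 0 genes and the InkArf split 0, which any of the 35 splits must match, so for genes the comparison says nothing about chance. The highest other count was 20, in the split by replicate number, which points to a structure of the samples other than genotype. For lists the Kras split gave 13, 6 of the 35 splits, itself included, gave as many, and the highest other gave 14. The InkArf split gave 6 lists, and 29 of the 35, itself included, gave as many, with 14 again the highest. For the list counts chance is excluded in neither.

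Outside Kras replicate 1, 10 genes lay at least 1 log2 unit outside the range of all other arrays. Apobec3, a restriction factor against retroviruses, was 10.70 in control replicate 2 and 7.40 to 8.16 elsewhere. The cell cycle gene Mki67 was 5.39 in control replicate 2, at least 6.41 elsewhere and 10.05 in Kras replicate 1. Its difference in Kras against control thus draws on both of these arrays. The cell cycle list lay at -0.61 in control replicate 2, -0.16 in control replicate 1 and -0.03 in Kras replicate 2. Ctla4, Tnfsf4 and Nid1 were highest in KrasInkArf replicate 1, with Ctla4 at 6.38 against at most 4.92. In InkArf replicate 2, H2-Eb1 was 9.58 and at least 12.46 elsewhere, D17H6S56E-5 was 5.90 and at least 9.11 elsewhere, and Vars, H2-DMb2 and a gene model were also lowest.

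Of the 5 genes lowest in InkArf replicate 2, 4 lie on chromosome 17 within a span of 42 measured genes around the class II region. Of 100000 random draws of 5 genes, 0 placed 4 so close (permutation p = 1e-05, the smallest these draws can give). The number of 4 and the span were read from these same genes. The p therefore describes how close they lie and does not test a cause. Another haplotype of this region in that sample is a candidate explanation, as probes that mismatch an allele read low. The test run first gave no support for it: among the 25 measured genes on each side of H2-Eb1, with the genes above left out, 0 stood apart by 0.5. That count was reached by 100% of windows. Its first rule counted that against a haplotype, and the permutation test was chosen after this outcome. Since the median window also holds 0, the first test cannot speak against a haplotype either, and other changes of the region stay open.

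A chromosome segment carried along with an altered allele would show as differences in genes beside it. Of the 50 measured genes around Kras, 2 had an unadjusted p under 0.01 in the Kras average, a count reached by 35.3% of windows: Klhl42, 19 genes away (1.02 ± 0.19, adjusted p = 0.312), and Pyroxd1 (0.41 ± 0.11, adjusted p = 0.365). Around Cdkn2a, 3 of 50 did in the InkArf average: Caap1 (-0.78 ± 0.15), Adamtsl1 (0.33 ± 0.09) and Tek (0.28 ± 0.08), each at limma adjusted p = 0.564. Adamtsl1 was also among the highest by moderated t in InkArf against control. The count was reached by 3.22% of windows. That is under the limit of 5% used first and over the 2.5% set for 2 loci after the count was seen, so a carried segment stays undecided at Cdkn2a, and at Kras too, where the count is above the median window of 1.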
